A study of Homo sapiens with 9 samples.

How the data were processed

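Total RNA from U-373MG cells was measured in 9 libraries, 3 untreated and 3 for each of the 2 peptides, given at 200 nM for 48 h. Per the labels and the design text, RNA was extracted with TRIzol, 500 ng entered each library and RNA integrity numbers were at least 9. Per the labels, the libraries were made with Lexogen's QuantSeq kit for the 3′ ends of messenger RNA and sequenced on an Illumina NextSeq 550 in single-end reads of 75 bp. Per the submitters' processing notes the tools were Bowtie2 and bedtools and the genome build was hg19, with versions, annotation and counting options not given in the sources used here. The files deposited by the authors hold raw read counts per gene symbol, 1 library per file, with no normalization. Per the labels' design text, the authors' own comparison used edgeR with TMM and CPM normalization, and no threshold is named there. The labels call the treated libraries biological replicates and do not say that each came from its own culture, so p-values measure the spread between these samples, which may be technical. All pairs of libraries differed by more than sampling noise, so each counted as 1 sample.

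The deposited counts have 25737 entries. A symbol that stood on several entries (286 symbols, 1561 entries) was summed, which left 24462 symbols. Total counts per library ranged from 11203094 to 13491075. Groups were taken from the labels alone. The gene lists, the rule for the genes named, the main tests and the alternatives were fixed before the data were examined, except where an alternative or test is said to have been chosen later.

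Genes were kept by filterByExpr of edgeR at its defaults (minimum count 10, minimum total 15) over the 3 groups, which left 13676. Counts were scaled by TMM and fitted with the quasi-likelihood model of edgeR 4.0.16 in R 4.3.3, all 9 libraries in 1 fit with a coefficient per group. The 3 comparisons were NnK-1 against control, CBRV1-10493 against control and CBRV1-10493 against NnK-1, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The common biological coefficient of variation was 0.169, and the median 95% interval of a log2 fold change at 5 CPM or more reached 0.33 to each side. CPM values are TMM-scaled, and errors are SDs over 3 libraries. The rule for the genes named took, for each peptide against control, from the passing genes with a mean of at least 5 CPM and no overlap between the groups, the 8 largest rises and 8 largest falls and the 4 of each with the smallest p (5, 5, 2 and 2 between the peptides). With fewer than 4 passing genes in a comparison it took the 4 higher and 4 lower genes with the smallest p as not passing. It always took every tested voltage-gated potassium channel gene and KCNA3, and up to 4 members with the smallest p in each list described; some of these genes are not reported here. A fold against a group at 0 was computed against 3 counts over the group.

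For gene groups 38 lists were fixed, from potassium channels to metabolism, cell cycle, stress, signalling and markers of cell types. The 36 lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with its preset correlation of 0.01, and adjusted over those lists; a list's mean and median are differences of log2 CPM. Camera with a correlation estimated per list and fry, which asks whether a list's genes move on balance 1 way, stand beside it. For the mitochondrially encoded transcripts 0 symbols were found, and of the immune cell markers 3 were tested, so neither list was tested.

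The main test was tested on simulated data drawn from the real means and library sizes, with 200 changed genes among 13676 in each of 5 simulations of NnK-1 against control. Of the genes changed 1.5-fold it recovered 37.0%, of those changed 2-fold 66.6% and of those changed 3-fold 79.1%; at 5 CPM or more these shares were 47.7%, 84.2% and 97.2%. Of 656 calls 48 were false (7.32%), and a list shifted by 0.3 on the log2 scale was recovered in 5 of 5 simulations. Genes were drawn independently there. The simulations therefore do not show how the list test behaves for smaller shifts or for genes that vary together. The correlation of the peptides' fold changes was set beside 40 simulations without a difference between groups. All 9 libraries were drawn anew, each gene independently, and the simulated controls served both peptides.

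The alternatives were DESeq2's size factors, upper-quartile factors, no filter on low counts, at least 5 CPM in 3 libraries, only the 6 libraries compared, an absolute log2 fold change of at least 1, a threshold of 0.01, the replicate number as a block, each library left out in turn, DESeq2 1.42.0 on all genes without the filter on low counts, edgeR's exact test and limma-voom. Alternatives chosen after seeing the data were limma-voom with library quality weights, DESeq2 on the genes kept by the filter and without independent filtering, edgeR's bias-adjusted quasi-likelihood fit with robust shrinkage, and leaving out both libraries that lay apart on the principal components. The reference used here for overlaps between genes and for the sequence of transcripts was of build GRCh38, not hg19, so no coordinates are given. Of 52 genes looked up 50 were matched, and 28 overlap another gene.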

Results

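U-373MG is an established human cell line of glioblastoma and astrocytoma origin. Its transcripts were counted in 3 groups of 3 libraries: untreated control cells, cells exposed for 48 h to 200 nM of the peptide NnK-1, and cells exposed for 48 h to 200 nM of the peptide CBRV1-10493. Both peptides are synthetic, come from jellyfish sequences and are described as ShK-like. ShK is a sea anemone toxin known to block the voltage-gated potassium channel Kv1.3. The same control libraries served for both peptides, and no time in culture is recorded for them in the sources used here. The libraries were made with QuantSeq, which reads near the 3′ ends of polyadenylated transcripts. The control libraries held 12306458, 12593112 and 13491075 counts, the NnK-1 libraries 12549625, 11203094 and 12125686, and the CBRV1-10493 libraries 12090415, 12211389 and 12116210. Between 15305 and 15968 genes had at least 1 read in a library, and 13676 genes were tested. The median correlation of log2 CPM was 0.973 between libraries of the same group and 0.973 between libraries of different groups, across genes, which are not independent replicates. On the first principal component (19.7% of the variance) NnK-1 replicate 2 lay apart at 52.1, and on the second (14.7%) CBRV1-10493 replicate 1 lay apart at -44.9.

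Transcripts of most voltage-gated potassium channels, the family that holds the ShK target Kv1.3, were scarce in these cells. KCNA3, which encodes Kv1.3, had 1 read over all 9 libraries, in NnK-1 replicate 2, and its count of 0 over the control group allows a level of up to 0.0781 CPM. Of the 38 voltage-gated potassium channel genes listed, 20 had no read in any library and 5 were tested. KCNS3, a modulatory subunit, was the one of these above 5 CPM, at 24.6 ± 3.07 CPM in control cells, 26.4 ± 4.43 with NnK-1 and 21 ± 2.34 with CBRV1-10493 (mean ± SD, n = 3). KCNC4 lay at 0.564 CPM, KCND1 at 0.611 CPM and KCNQ5 at 1.20 CPM in control cells. Limits derived from a count of 0 cover counting error only. The scarcity is stated for the voltage-gated family alone: of 39 other potassium channel genes listed, 13 were tested, KCNN4 among them.

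The first comparison asked which transcripts differ between cells exposed to NnK-1 and untreated cells. CRY1, a repressor of the circadian clock, stood at 17.3 ± 1.39 CPM with NnK-1 and 8.0 ± 2.73 CPM in control cells, a log2 fold change of 1.11 (95% interval 0.60 to 1.63, n = 3). SCARNA22, a small Cajal body RNA, stood at 75.1 ± 11.4 against 119 ± 9.69 CPM (log2 fold change -0.67), and RNU4ATAC, a small nuclear RNA of the minor spliceosome, at 85.5 ± 5.29 against 162 ± 50.8 CPM (-0.92). These genes had the smallest p-values, each with every NnK-1 library on 1 side of every control library, yet no gene passed the test after adjustment. As groups, interferon-stimulated genes were lower with NnK-1 and cholesterol synthesis genes were higher, by camera with its preset correlation. Neither call held with an estimated correlation (adjusted p = 0.925 and adjusted p = 0.441) or by fry. The estimated correlation was 0.357 for the interferon genes. For the cholesterol genes it was -0.0046, below the preset 0.01, so genes that vary together do not explain why their camera call was lost. The interferon call ended without control replicate 2 (adjusted p = 0.932) or NnK-1 replicate 1 (adjusted p = 0.147), and the cholesterol call ended without these or control replicate 3 while its mean stayed between 0.12 and 0.16 under all 15 alternatives (0.14 with all libraries).

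Among the 4 genes with the smallest p in each direction, none of which passed, PPP2R2B, a regulatory subunit of protein phosphatase 2A, stood at 218 ± 6.65 with NnK-1 against 166 ± 1.47 CPM (log2 fold change 0.39, interval 0.21 to 0.58). RTCB, the ligase of tRNA splicing, stood at 103 ± 6.57 against 72.9 ± 7.36 CPM (0.49), and the small nucleolar RNA host gene SNHG19 at 145 ± 27.7 against 97.0 ± 5.68 CPM (0.58). On the lower side, PCMTD1 stood at 19.7 ± 2.02 against 32.8 ± 3.62 CPM (-0.74, interval -1.06 to -0.42). IFI44L, an interferon-induced gene, stood at 2.54 ± 0.551 against 16.4 ± 19.6 CPM (-2.68), with 35, 32 and 23 counts in the NnK-1 libraries and 48, 497 and 84 in the control libraries. SCARNA22 lies within NSD2, RNU4ATAC within CLASP1 and SNHG19 overlaps SNORD60, and the rule by which overlapping genes were counted is not given in the sources used here, so these values are uncertain. By edgeR's quasi-likelihood test 0 genes were higher and 0 lower, with a smallest adjusted p of 0.499. At an unadjusted p under 0.05 there were 1001 genes (514 higher, 487 lower) where 684 are given by chance, and the NnK-1 and control libraries were fully separated for 12.9% of genes where chance gives 10%. DESeq2 passed 2 genes of the 18756 it tested without the filter on low counts (PPP2R2B higher, SCARNA22 lower) and 3 of the 13676 genes kept by the filter (these and PCMTD1, lower). Passing genes numbered 8 (3 higher, 5 lower) by edgeR's exact test, 0 by limma-voom and 0 by limma-voom with library quality weights. Without a filter on low counts edgeR's quasi-likelihood test passed 27 higher and 47 lower, RNU4ATAC, IFI44L and SCARNA22 among them. In that setting, in all comparisons, the spread of single genes no longer counted.

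**Figure D1:**
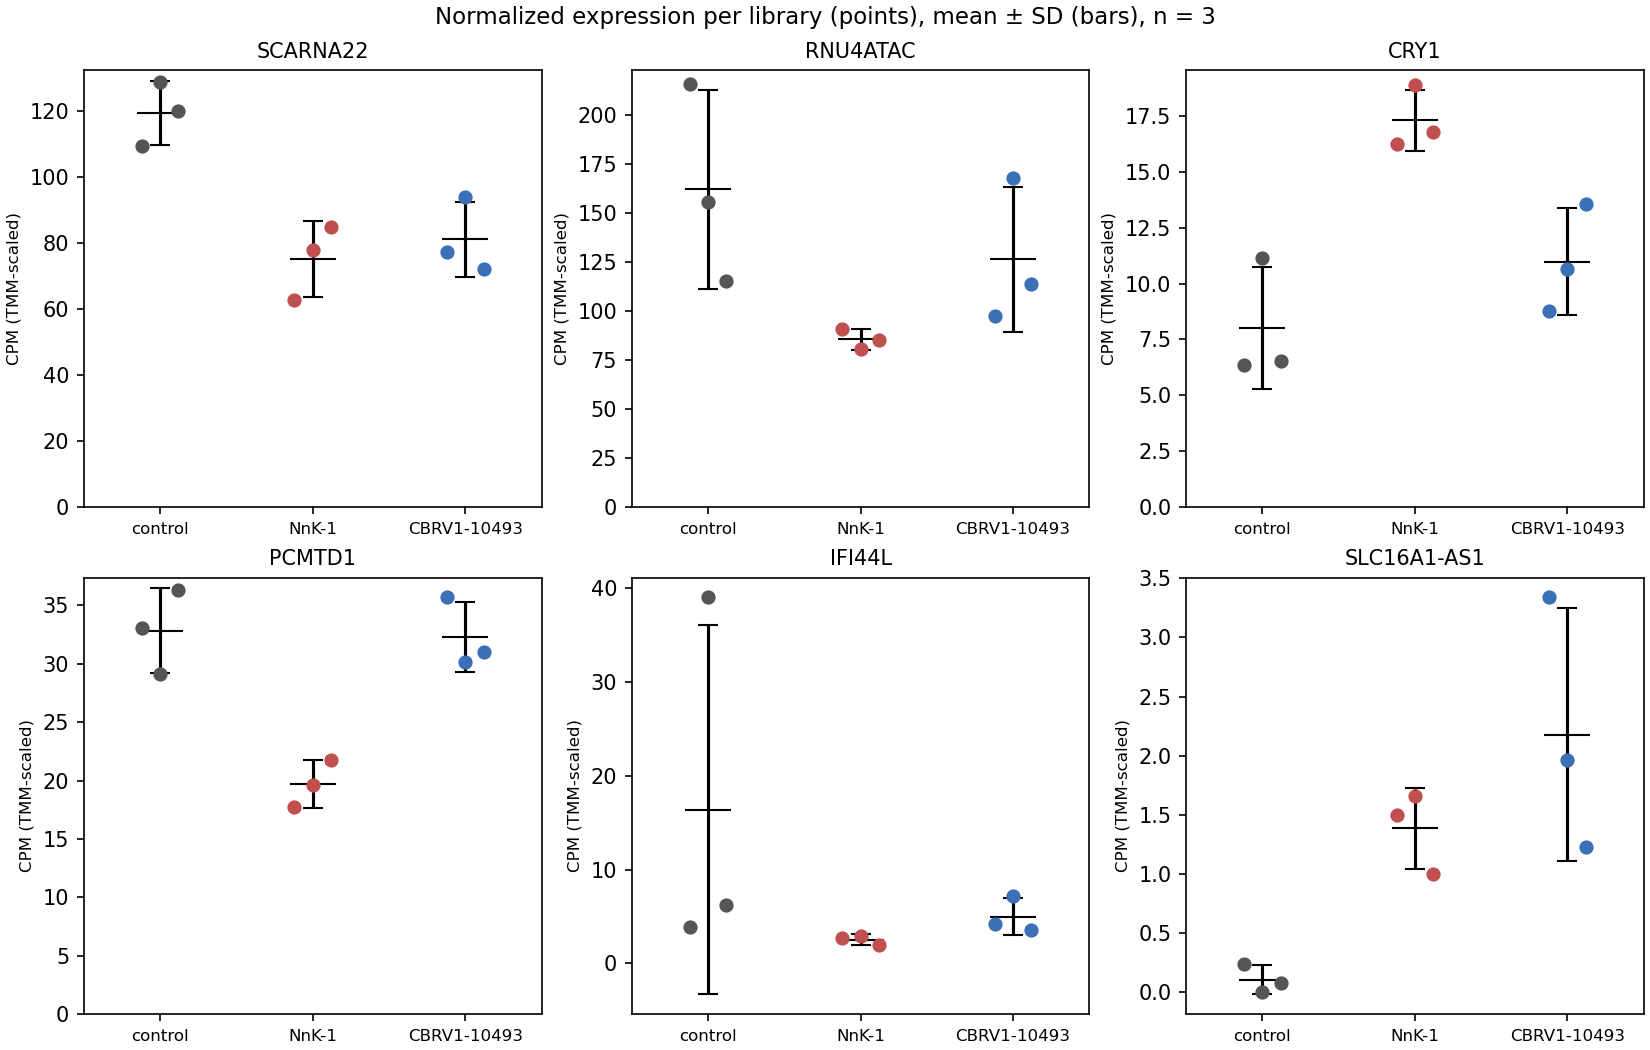
Normalized expression in CPM (vertical axes) of 6 genes in each library of the control, NnK-1 and CBRV1-10493 groups; points are libraries, long ticks the mean and bars the SD (n = 3). SCARNA22 lies at 119 CPM on average in control cells and at 75.1 and 81.0 CPM with the peptides, and the IFI44L mean of the control group rests on 1 library at 39.0 CPM.

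Interferon-stimulated genes were lower as a group with NnK-1: 27 of the 34 tested members had a log2 fold change below 0, and the mean difference was -0.41 (median -0.23). Camera gave an adjusted p of 0.00363 with its preset correlation and an adjusted p = 0.925 with an estimated correlation. No member passed over all genes, and 3 passed when adjusted over the list alone. Next to IFI44L, the smallest p-values belonged to SAMD9 (24.0 ± 3.59 against 38 ± 8.92 CPM, log2 fold change -0.66), BST2, which tethers virus particles to the cell surface (2.16 ± 0.533 against 8.64 ± 7.71 CPM, -2.00), and the antiviral GTPase MX1 (7.28 ± 1.73 against 20.9 ± 23.1 CPM, -1.52). In control replicate 2 MX1 stood at 47.6 CPM against 6.57 and 8.66 CPM in the other two control libraries. Without that library the log2 fold change was -0.064 for MX1, -0.46 for SAMD9, -0.96 for BST2 and -0.99 for IFI44L. The mean difference of the list was then -0.073 (adjusted p = 0.932), and without NnK-1 replicate 1 it was -0.45 (adjusted p = 0.147).

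Cholesterol synthesis genes were higher as a group with NnK-1: 20 of 24 tested members lay above 0, with a mean log2 difference of 0.14 (median 0.11). The adjusted p was 0.0256 with the preset correlation of camera and the adjusted p = 0.441 with an estimated correlation. No member passed over all genes, and 1 passed when adjusted over the list alone. DHCR7, a reductase of the last steps of the pathway, stood at 121 ± 15.2 against 94.1 ± 4.36 CPM (log2 fold change 0.36, interval 0.11 to 0.61). STARD4, a sterol carrier, stood at 7.83 ± 1.99 against 4.60 ± 0.571 CPM (0.77), and the demethylase CYP51A1 at 109.9 ± 7.10 against 92.7 ± 4.44 CPM (0.25). The mean stayed between 0.12 and 0.16 under all 15 alternatives, while the adjusted p missed the threshold without control replicate 2 (mean 0.13, adjusted p = 0.352), control replicate 3 (mean 0.14, adjusted p = 0.0620) or NnK-1 replicate 1 (mean 0.12, adjusted p = 0.197).

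**Figure D2:**
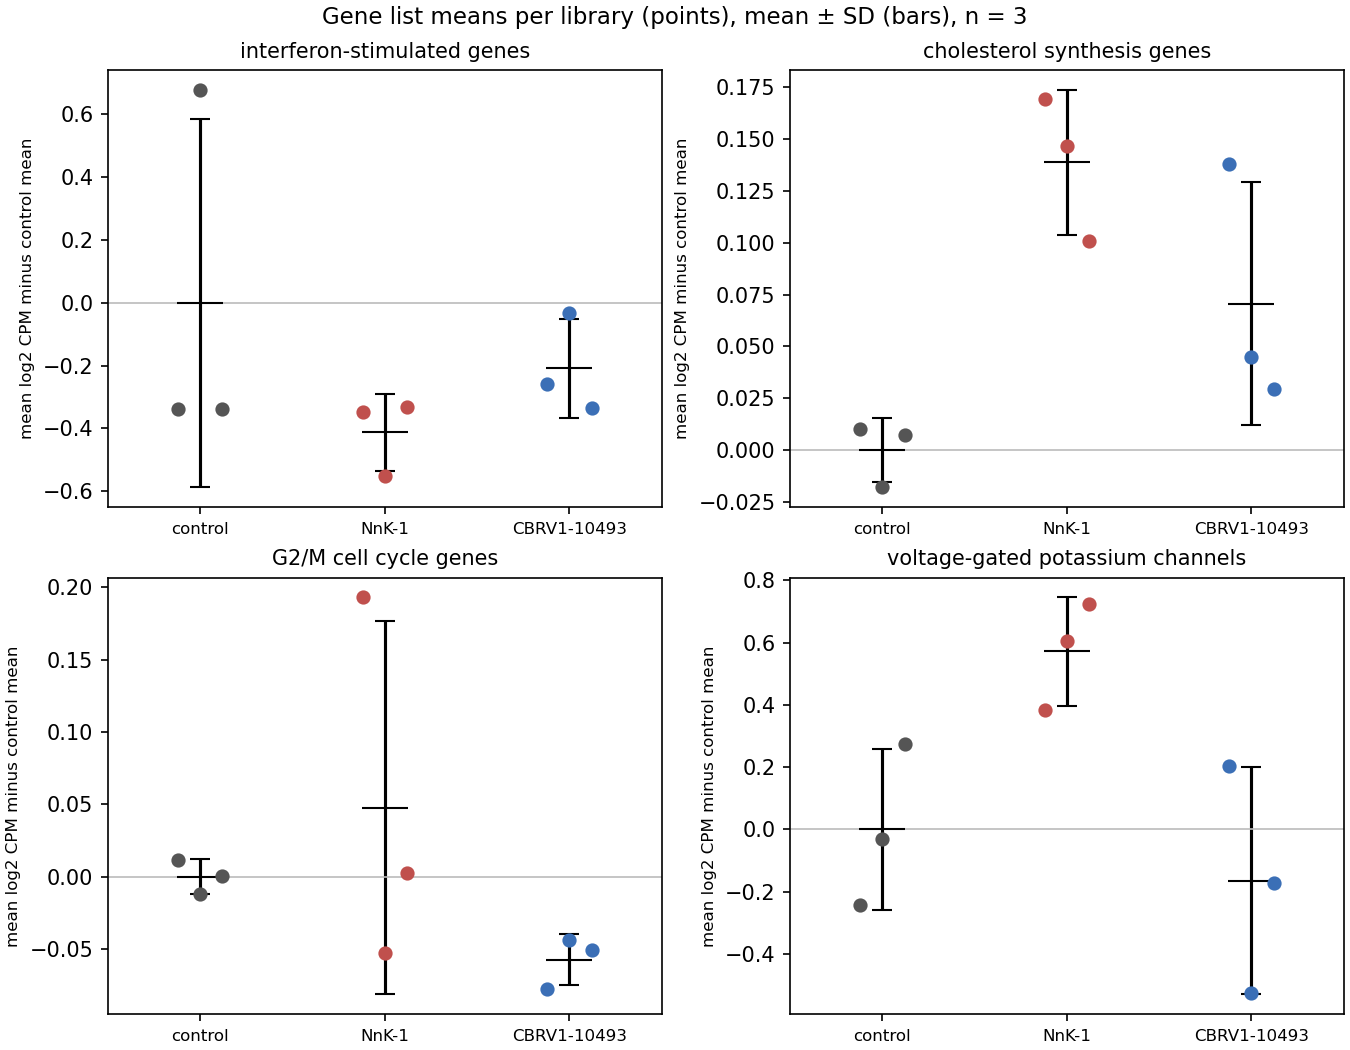
Mean log2 CPM of 4 gene lists in each library, relative to the mean of the 3 control libraries (vertical axes), for control, NnK-1 and CBRV1-10493; points are libraries, long ticks the mean and bars the SD (n = 3). Control replicate 2 lies at 0.68 for interferon-stimulated genes while the other control libraries lie at -0.34, and NnK-1 replicate 1 lies at 0.19 for G2/M genes.

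The other 34 lists were not called for NnK-1 against control, with adjusted p from 0.125 to 0.998. The 5 tested voltage-gated potassium channel genes had a mean log2 difference of 0.57 (adjusted p = 0.125), with KCNQ5 at 1.31 (interval -0.04 to 2.66, and 0.71 to 1.73 over the alternatives), KCNC4 at 1.03, KCNS3 at 0.10 (-0.017 without NnK-1 replicate 2) and KCND1 at -0.09, which kept its sign in 12 of 19 alternatives (-0.90 to 0.78). Without NnK-1 replicate 2 the mean of this list was -0.0056, while without CBRV1-10493 replicate 2 it was called at 0.89 (adjusted p = 0.0127). Genes of hypoxia and glycolysis had a mean of 0.06 (adjusted p = 0.232, mean 0.037 to 0.086 over the alternatives). Among them KDM3A, a histone demethylase, stood at 0.35 and the glycolytic enzyme GAPDH at -0.19. For the nuclear genes of the respiratory chain 51 of 76 lay above 0 (mean 0.04, adjusted p = 0.252), with ATP5L at 0.28 and NDUFA3 at 0.39 (0.19 without NnK-1 replicate 2). For G2/M genes 33 of 47 lay above 0 (mean 0.05, adjusted p = 0.252), and without NnK-1 replicate 1 the mean was -0.028. This list was called higher at 0.10 without NnK-1 replicate 2 (adjusted p = 0.0185) and without both libraries that lay apart (adjusted p = 0.0257). Genes of the cytoskeleton and focal adhesion went both ways (mean -0.04, adjusted p = 0.926, mean -0.093 to -0.037 over the alternatives). The actin crosslinker FLNA stood at 662 ± 22.9 against 898 ± 50.1 CPM (log2 fold change -0.44) and ACTG1, a cytoplasmic actin, at 0.26. FLNA passed when adjusted over the list alone, as 1 gene of 39. The 7 lists of stress and cell death had adjusted p from 0.346 to 0.989 and the 6 lists of signalling from 0.677 to 0.989. Glial and progenitor markers (2 lists) ranged from 0.775 to 0.926, and markers of neurons, oligodendrocytes, endothelial cells and epithelial cells (4 lists) from 0.388 to 0.926. Mean, median and test differed in sign for 10 lists, none of them called.

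The second comparison asked which transcripts differ between cells exposed to CBRV1-10493 and untreated cells. SCARNA22 was again among the genes with the smallest p, at 81.0 ± 11.3 CPM with CBRV1-10493 against 119 ± 9.69 CPM in control cells (log2 fold change -0.56, interval -0.82 to -0.29, n = 3). TSHZ3, a zinc finger transcription factor, stood at 5.39 ± 0.674 against 11.6 ± 1.49 CPM (-1.10), and the zinc finger gene ZNF133 at 20.6 ± 3.11 against 11.9 ± 1.35 CPM (0.79). None of these genes passed the test after adjustment, and no gene list was called.

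On the higher side, the antisense transcript SLC16A1-AS1 had 40, 24 and 15 counts with CBRV1-10493 and 3, 0 and 1 in control libraries (log2 fold change 4.26, interval 2.40 to 6.12). The noncoding RNA LINC01358 had 18, 17 and 4 counts against 0, 0 and 0, which is at least 13.8-fold higher against 3 counts over the control group. GCOM1, a locus that overlaps MYZAP and POLR2M, stood at 79.1 ± 9.60 against 58.5 ± 3.48 CPM (0.43). On the lower side, the uncharacterised loci LOC100129940 and LOC100506022 had log2 fold changes of -1.21 and -2.87, the latter from 4, 1 and 4 counts against 31, 25 and 16. By edgeR's quasi-likelihood test 0 genes were higher and 0 lower, with a smallest adjusted p of 1.00. At an unadjusted p under 0.05 there were 395 genes (183 higher, 212 lower), fewer than the 684 given by chance, and 8.96% of genes had fully separated groups where chance gives 10%. DESeq2 passed 0 genes with and without the filter on low counts, edgeR's exact test 2 (SLC16A1-AS1 and LINC01358, both higher), limma-voom 0 and limma-voom with library quality weights 0. Without a filter on low counts edgeR's quasi-likelihood test passed 1 higher and 5 lower.

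Of the 36 lists tested, the smallest adjusted p by camera was 0.191, shared by 2 lists. In the nuclear genes of the respiratory chain 56 of 76 members lay above 0 (mean log2 difference 0.05), with NDUFA1 at 0.12 and ATP5C1 at 0.15, and in the G2/M genes 34 of 47 lay below 0 (mean -0.06), with PTTG1 at -0.24 and the kinesin KIF11 at -0.29. Interferon-stimulated genes had 25 of 34 members below 0 and a mean of -0.21 (adjusted p = 0.317), with IFI44L at 5.0 ± 1.93 against 16.4 ± 19.6 CPM (-1.71), BST2 at -1.49, MX1 at -1.38 and IFI6 at -0.69; without control replicate 2 IFI44L was at -0.013, BST2 at -0.45, MX1 at 0.077 and IFI6 at -0.11. This list depended on control replicate 2: its mean was 0.13 without that library, while it was called at -0.38 without control replicate 1 (adjusted p = 0.0147) or control replicate 3 (adjusted p = 0.00204). Cholesterol synthesis genes had 19 of 24 members above 0 (mean 0.07, adjusted p = 0.349, mean 0.037 to 0.089 over the alternatives). Among them DHCR7 stood at 0.20 (0.087 without CBRV1-10493 replicate 1) and the decarboxylase MVD at 0.46 (0.22 without CBRV1-10493 replicate 3). The other potassium channels had a mean of 0.12 (adjusted p = 0.349), with KCNN3, a calcium-activated channel, at 9.57 ± 0.715 against 5.55 ± 0.893 CPM (0.79, interval 0.24 to 1.33) and the inward rectifier KCNJ2 at 0.79. This list was called at 0.31 with at least 5 CPM required in 3 libraries (adjusted p = 0.0302), while its mean was 0.029 without control replicate 2 (adjusted p = 0.756). Of the voltage-gated channels, KCNS3 stood at -0.23 (-0.32 to -0.14 over the alternatives) and KCNC4 at 0.67. KCNQ5 stood at 0.43 (0.053 without control replicate 1) and KCND1 at -0.99 (-0.23 without control replicate 3). All 11 counts of KCND1 with CBRV1-10493 lay in replicate 1, and without that library its fitted value was -5.94. No list had a member that passed when adjusted over the list alone. The 7 lists of stress and cell death had adjusted p from 0.647 to 0.988, the 6 lists of signalling from 0.781 to 0.988, the glial and progenitor markers (2 lists) from 0.542 to 0.781, and the markers of 4 other cell types from 0.349 to 0.988. Mean, median and test differed in sign for 9 lists.

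**Figure D3:**
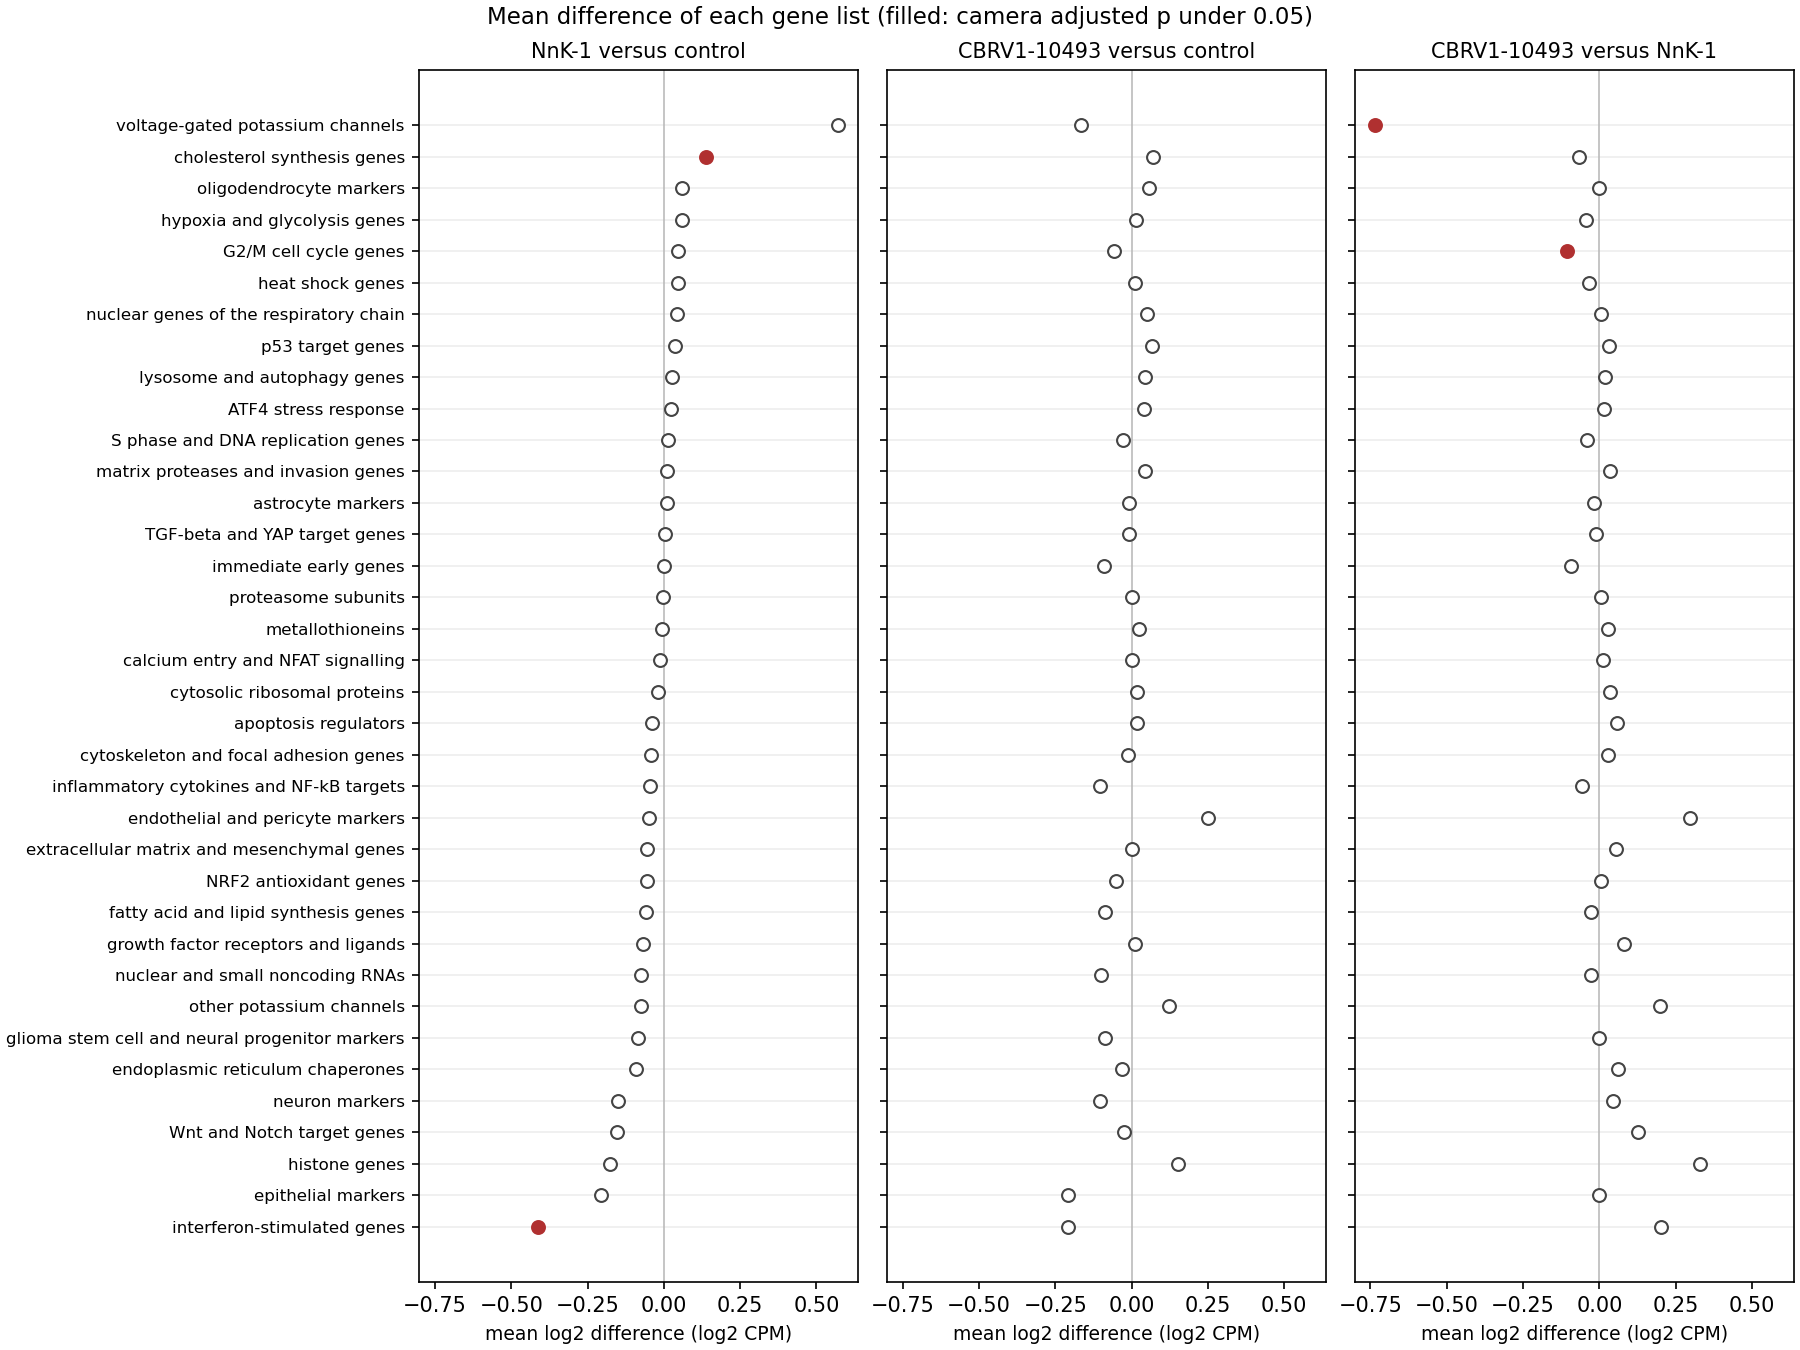
Mean log2 difference of each of the 36 tested gene lists (horizontal axes, log2 CPM) in the 3 comparisons; each point is a list, filled where camera gave an adjusted p under 0.05 with its preset correlation. Filled points mark 2 lists for NnK-1 against control, 0 for CBRV1-10493 against control and 2 for CBRV1-10493 against NnK-1.

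The third comparison set the peptides against each other at the same dose and time. PCMTD1 was at 32.3 ± 3.01 CPM with CBRV1-10493 against 19.7 ± 2.02 CPM with NnK-1 (log2 fold change 0.71, interval 0.39 to 1.03, n = 3), CGN, which encodes the tight junction protein cingulin, at 4.17 ± 0.762 against 1.37 ± 0.111 CPM (1.60), and the actin-binding COTL1 at 312 ± 29.4 against 401 ± 34.2 CPM (-0.36). None of these passed after adjustment. As groups, G2/M genes and the tested voltage-gated potassium channel genes were lower with CBRV1-10493 than with NnK-1, by camera with its preset correlation. Neither call held with an estimated correlation (adjusted p = 0.660 for each) or by fry.

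Of the remaining genes with the smallest p, C10orf11 stood at 45.5 ± 2.67 against 30.3 ± 3.09 CPM (0.58) and the noncoding HCG18, which overlaps TRIM39, at 8.72 ± 1.27 against 4.46 ± 0.342 CPM (0.96). PNKD, which overlaps TMBIM1, stood at 33.2 ± 5.45 against 50.7 ± 9.07 CPM (-0.61), EIF3J-AS1 at -0.68 and RNASEH2B-AS1, which overlaps RNASEH2B, at -4.00 from 0, 1 and 3 counts against 24, 30 and 13. By edgeR's quasi-likelihood test 0 genes were higher and 0 lower, with a smallest adjusted p of 0.994. At an unadjusted p under 0.05 there were 589 genes (268 higher, 321 lower) where 684 are given by chance, and 8.82% of genes had fully separated groups where chance gives 10%. DESeq2 (with and without the filter on low counts), edgeR's exact test, limma-voom and limma-voom with library quality weights each passed 0 genes, and without a filter on low counts edgeR's quasi-likelihood test passed 1 gene, RNU4ATAC (0.56). For the 10617 genes at 5 CPM or more, the median 95% interval of the difference between the peptides reached 0.33 on the log2 scale to each side, so the values do not show that the peptides act alike. When NnK-1 replicate 1 and CBRV1-10493 replicate 1 changed places, 136 genes passed.

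G2/M genes were lower as a group with CBRV1-10493 than with NnK-1: 39 of 47 members lay below 0 (mean log2 difference -0.10, adjusted p = 0.000255, and adjusted p = 0.660 with an estimated correlation). No member passed, over all genes or adjusted over the list alone (0 of 47). The smallest p-values were those of CKS1B, a cofactor of cyclin-dependent kinases (105 ± 1.78 against 132 ± 8.03 CPM, -0.33), the kinesin KIF2C (67.2 ± 7.35 against 87.0 ± 8.41 CPM, -0.37), the mitotic cyclin CCNB1 (-0.30) and the checkpoint gene BUB3 (-0.26). Over the alternatives BUB3 ranged from -0.34 to -0.15. NnK-1 replicate 1 lay at 0.19 for this list relative to control, NnK-1 replicates 2 and 3 at -0.05 and 0.00, and the CBRV1-10493 libraries at -0.08, -0.04 and -0.05. Without NnK-1 replicate 1 the mean difference was -0.031 (adjusted p = 0.521).

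All 5 tested voltage-gated potassium channel genes lay below 0, with a mean log2 difference of -0.74 (adjusted p = 0.0296, and adjusted p = 0.660 with an estimated correlation). KCND1 stood at -0.90, KCNQ5 at -0.88, KCNC4 at -0.35 and KCNS3, the one above 5 CPM, at -0.33 (interval -0.68 to 0.03). Over the alternatives these values ranged from -5.86 to -0.087 for KCND1, from -1.61 to -0.28 for KCNQ5, from -0.56 to -0.10 for KCNC4 and from -0.45 to -0.13 for KCNS3, and 0 of the 5 passed, over all genes or adjusted over the list alone. The call held in 3 of 14 alternatives. It ended without each of the control and NnK-1 libraries, CBRV1-10493 replicate 1 or CBRV1-10493 replicate 3, with means from -0.62 without CBRV1-10493 replicate 3 (adjusted p = 0.0684) to -0.024 without NnK-1 replicate 2 (adjusted p = 0.851), and the mean was 0.13 without both libraries that lay apart on the principal components.

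The other 34 lists were not called for CBRV1-10493 against NnK-1, with adjusted p from 0.179 to 0.989. Interferon-stimulated genes had 27 of 34 members above 0 (mean 0.20, adjusted p = 0.179, mean 0.11 to 0.26 over the alternatives). SAMD9 stood at 32.2 ± 4.50 against 24.0 ± 3.59 CPM (0.42). The RNA sensor DDX58 stood at 0.57 (0.34 to 0.69 over the alternatives) and DTX3L, which overlaps PARP9, at -0.23 (-0.32 to -0.14). Histone genes had 13 of 16 members above 0 (mean 0.33, adjusted p = 0.179), with HIST1H1C at 133 ± 9.13 against 111 ± 7.32 CPM (0.26). The mean of the histone genes was 0.17 without CBRV1-10493 replicate 1, 0.16 without NnK-1 replicate 2, 0.026 without both libraries and 0.11 with at least 5 CPM required in 3 libraries. Cholesterol synthesis genes had 17 of 24 members below 0 (mean -0.07, adjusted p = 0.358), with HMGCS1 at -0.22 (-0.33 to -0.14 over the alternatives) and FDFT1 at -0.17. The 7 lists of stress and cell death had adjusted p from 0.672 to 0.876, the 6 lists of signalling from 0.627 to 0.974, the glial and progenitor markers (2 lists) from 0.954 to 0.974, and the markers of 4 other cell types from 0.360 to 0.974. Mean, median and test differed in sign for 5 lists, none of them called. In none of the 3 comparisons did a list pass with an estimated correlation or by fry, whose smallest adjusted p was 0.0899, for the cholesterol synthesis genes with NnK-1.

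The log2 fold changes of the peptides against the shared control libraries had a Pearson correlation of 0.511 across the 13676 tested genes. Unchanged groups simulated against the same controls gave 0.497 ± 0.0148 (SD over 40 simulations), with 5 of 40 at least as large as the observed value. The covariance was 0.0713 against 0.0524 ± 0.00233 in the simulations, a difference of 0.0189, and in 0 of 40 simulations was it as large. The simulations drew each gene independently and did not use the real control libraries. Their spread may therefore be too narrow to judge this difference. The simulated counts were also filtered again, which in the simulations of the main test left 13460 to 13485 of 13676 genes. The simulated and observed values may therefore cover unlike sets of genes. The control group of 3 cannot be split into parts of at least 2 libraries, so part of the excess may come from the shared controls. At an unadjusted p under 0.05, 130 genes lay on the same side of control with both peptides, 66 higher and 64 lower, where the simulations gave 130.1 on average (106 to 157) and independent lists give 6.88 higher and 7.55 lower. None lay on opposite sides (0 genes, 0.575 in the simulations), and 0 genes passed in both comparisons, where the simulations gave 0.075, edgeR's quasi-likelihood test having passed 0 for each peptide. SLC16A1-AS1 passed edgeR's exact test for both peptides, and without a filter on low counts 6 genes passed the quasi-likelihood test for both, in the same direction. They were IFI44L, MX1, IFI6, CD70, SCARNA22 and SLC16A1-AS1. Without that filter the spread of single genes no longer counted. The control libraries were shared, so the common direction of these genes is not independent support for a common response. With CBRV1-10493 and without control replicate 2, IFI44L stood at -0.013, MX1 at 0.077 and IFI6 at -0.11. The simulations kept the filter, so they give no value for unchanged groups in this setting.

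**Figure D4:**
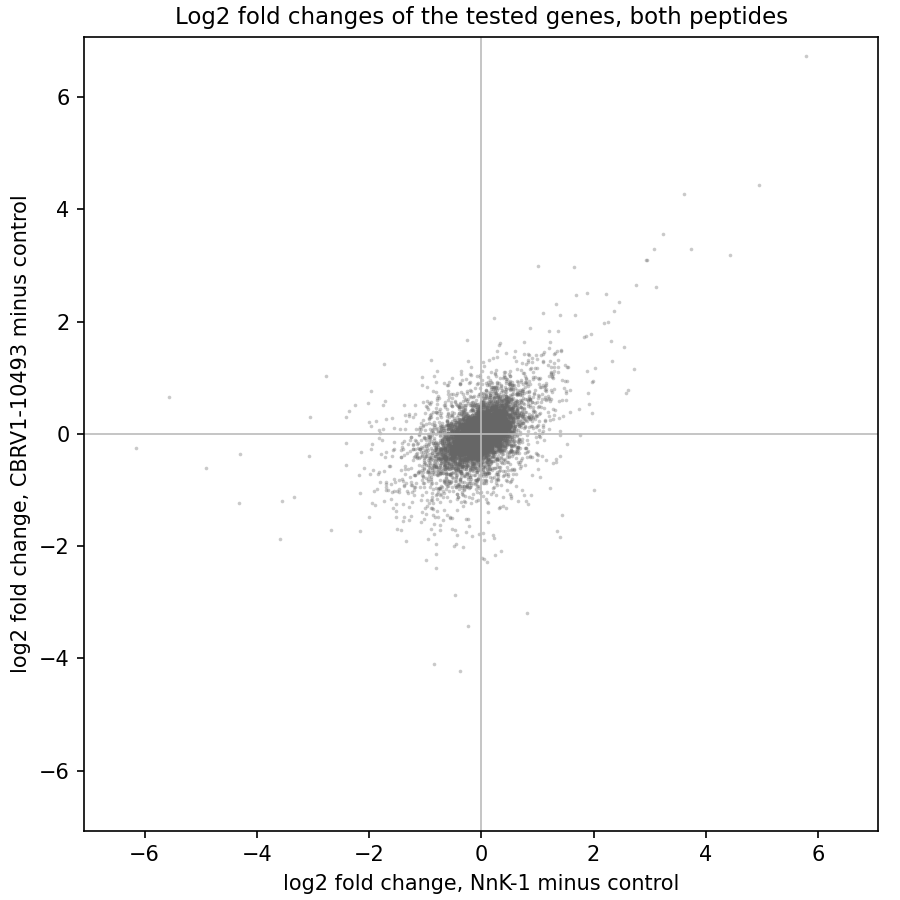
Log2 fold changes of the 13676 tested genes for NnK-1 minus control (horizontal axis) and CBRV1-10493 minus control (vertical axis); each point is a gene, and grey lines mark 0. The correlation is 0.511, and 0.497 in simulated unchanged groups that share simulated controls.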

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

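The tests of correlated expression, of the S phase genes and of an exchange of 2 libraries were chosen after the result was seen. So were the exchanges of libraries themselves. The test of GC content was set before GC content was computed, but for genes that a result already seen had picked. The other tests were chosen before.

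Between the peptides, 2 gene lists differed by a test of the difference itself. The 5 tested voltage-gated potassium channel genes were lower with CBRV1-10493 than with NnK-1, with a mean log2 difference of -0.74 (camera adjusted p = 0.0296, and adjusted p = 0.660 with an estimated correlation; over 14 alternatives the adjusted p ranged from 0.0333 to 0.969), and 4 of the 5 lay at 3.00 CPM or less in every group. G2/M genes were lower with CBRV1-10493, with a mean log2 difference of -0.10 (adjusted p = 0.000255, and adjusted p = 0.660 with an estimated correlation).

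For the G2/M genes, the call ended when NnK-1 replicate 1 was left out (mean -0.031, adjusted p = 0.521), the library that lay highest for this list at 0.19. It also ended with the correlation estimated from the data (adjusted p = 0.660), while it held in 12 of 15 alternatives, over which the adjusted p ranged from 4.50e-07 to 0.660. The estimated correlation of these genes was 0.093, above the preset 0.01. The same test also ended the call of cholesterol synthesis genes with NnK-1, whose estimate was -0.0046. Losing the call in it is therefore not by itself evidence that genes vary together. Both explanations, 1 library and genes that vary together, may account for the call, and they do not exclude each other. Fewer dividing cells with CBRV1-10493 would also lower genes of S phase, whose list had a mean of -0.04 and was not called (adjusted p = 0.627); this stays open, since a p that misses the threshold does not show that S phase genes were alike.

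In the direct comparison, the 10 splits of the 6 libraries are too few for a share under 0.05: the real split gave 589 genes at an unadjusted p under 0.05 and the highest other 1882, with 6 splits as large counting the real one, and 2 lists against 1 at most elsewhere, with 1 split as large. The split that set NnK-1 replicates 2 and 3 with CBRV1-10493 replicate 1 against the rest passed 136 genes in edgeR. The split by the labels passed 0. This points to a structure of the samples that the peptide labels do not follow. For NnK-1 against control, likewise 10 splits, the real split gave 1001 genes and the highest other 1428 (3 as large), and 2 lists where the highest other gave 2 (5 as large). For CBRV1-10493 against control it gave 395 genes and the highest other 809 (6 as large), and 0 lists where the highest other gave 1 (10 as large).

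Of the 136 genes, 45 were higher and 91 lower in NnK-1 replicates 2 and 3 and CBRV1-10493 replicate 1, and among 27 exchanges of 1 library between 2 groups no other passed more than 1 gene in any comparison. The same exchange passed 135 genes for NnK-1 against control (1832 at an unadjusted p under 0.05) and 0 for CBRV1-10493 against control (501 at an unadjusted p under 0.05, by edgeR's quasi-likelihood test). For the 136 genes, the median GC content of the last 500 bases of the transcripts was 47.7% for those higher and 40.1% for those lower, against 41.8% for all tested genes. The difference was -7.6 percentage points (permutation p = 0.00894, two-sided, 100000 resamples over genes). These genes were selected together and are not independent, and GNG10 and DNAJC25-GNG10, for example, had near-identical values. This p therefore does not measure the spread between libraries. A difference between libraries that follows sequence composition may be part of this structure. An exchange of the 2 libraries would make both correlate more with the other peptide's libraries than with their own: the difference in mean r was 0.00612 for NnK-1 replicate 1 and -0.00129 for CBRV1-10493 replicate 1. An exchange and a difference in handling cannot be told apart, since these differences are small and of opposite sign, and no biological explanation was tested.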

How the results depend on the processing

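Limma-voom with library quality weights, DESeq2 on the filtered genes, the bias-adjusted robust fit and the fit without both libraries that lay apart were chosen after seeing the data; the other alternatives were chosen before. Of the fold changes of named genes, 1953 values kept their direction and side of the threshold, 29 passed in addition and 10 changed sign; of the list means, 221, 6 and 4, and 22 lost the call. Of the 92 fold changes 39 moved by over 1.5 times in at least 1 alternative. Of the counts of calls 170 stayed and 32 moved. At this depth and 3 libraries a group, a 1.5-fold change was recovered for 37.0% of genes in the simulations of NnK-1 against control.

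Genes passing numbered 0 in each comparison under both other scalings, the filter at 5 CPM, fits of 6 libraries, each library left out, limma-voom and 3 of the 4 alternatives chosen later. Both stricter thresholds gave 0 as well, which was fixed in advance, since no gene passed the main threshold in the same fit. Without a filter on low counts NnK-1 passed 27 higher and 47 lower, CBRV1-10493 1 and 5, and the direct comparison 1 higher; all had been tested with the filter, and the prior degrees of freedom had gone from 13.6 to infinite, so the spread of single genes no longer counted. DESeq2, run without the filter, passed 1 higher and 1 lower for NnK-1, and on the filtered genes 1 higher and 2 lower; edgeR's exact test passed 3 higher and 5 lower for NnK-1 and 2 higher for CBRV1-10493. The cause was not tested for these tools.

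When each library was left out, lists called ranged from 0 (without control replicate 2 or NnK-1 replicate 1) to 3 (without NnK-1 replicate 2 or CBRV1-10493 replicate 2) for NnK-1, from 0 to 1 (without control replicate 1 or 3) for CBRV1-10493 and from 0 (without NnK-1 replicate 1) to 2 between the peptides. With an estimated correlation and by fry 0 lists were called in each comparison. The filter at 5 CPM called 1 for CBRV1-10493 and 1 between the peptides, where fewer genes were tested and the voltage-gated channels were too few to test; leaving out both libraries that lay apart called 3 for NnK-1 and 1 between the peptides. When each library was left out, the mean of interferon-stimulated genes for CBRV1-10493 ranged from -0.38 (without control replicate 1) to 0.13 (without control replicate 2), of G2/M genes for NnK-1 from -0.028 (without NnK-1 replicate 1) to 0.10 and of voltage-gated channels for NnK-1 from -0.0056 (without NnK-1 replicate 2) to 0.89; between the peptides the mean of these channels was 0.13 without both libraries that lay apart. The log2 fold change with NnK-1 ranged from -0.90 (without NnK-1 replicate 2) to 0.67 for KCND1 and from -0.017 (without NnK-1 replicate 2) to 0.22 for KCNS3, and MX1 with CBRV1-10493 from -1.84 to 0.077 (without control replicate 2). KCNS3 was at -0.017 without both libraries that lay apart, and KCND1 at 0.66 by limma-voom and 0.78 with quality weights. The correlation of the peptides' fold changes ranged from 0.365 (without NnK-1 replicate 1) to 0.645 (without control replicate 1), and was 0.360 without both that lay apart and 0.539 at 5 CPM. Since the controls are shared, fewer control libraries raise this correlation and fewer peptide libraries lower it, even without an effect. Each fit without a control library gave 0.580 or more, and each without a peptide library 0.437 or less. Otherwise the cause of the changes was not tested.

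Replicate numbers did not pair the samples: same-numbered libraries of different groups had correlations from -0.057 to 0.132, others from -0.093 to 0.097, and 4 of 9 libraries correlated best with their own number. With the replicate block 0 genes passed in each comparison, KCND1 with NnK-1 stood at 0.25 (reversed from -0.09) and the correlation was 0.508; no list gained or lost its call.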

Other observations

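The test of control replicate 2 was chosen after the result was seen, as were the sums over small RNA classes and the genes named here. The count of members below the other control libraries was set before it was made. It leaves out control replicate 2, however, and that choice rests on values already seen.

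The fixed list of nuclear and small noncoding RNAs was not called (camera adjusted p = 0.874 for NnK-1, with 9 members above 0 and 13 below, and adjusted p = 0.349 for CBRV1-10493). Summed by class, counts at symbols of small nucleolar and small Cajal body RNAs were lower in the peptide libraries than in the control libraries. QuantSeq reads near the 3′ ends of polyadenylated transcripts, so these counts may come from genes that overlap the symbols, as NSD2 overlaps SCARNA22. The sums may therefore not measure the small RNAs themselves. Small Cajal body RNAs (24 symbols) summed to 171 ± 18.7 CPM in control cells, 108 ± 18 with NnK-1 and 116 ± 13.5 with CBRV1-10493 (SD, n = 3), and small nucleolar RNAs (371 symbols) to 140.0 ± 18.2, 110.3 ± 3.16 and 113 ± 10.6 CPM. SCARNA22 alone made up 119, 75.1 and 81.0 CPM of the small Cajal body RNAs, and the others summed to 52.1 ± 10.8, 33.1 ± 8.12 and 34.7 ± 2.25 CPM, with the lowest control library at 43.2 and the highest peptide library at 42.4 CPM. Each of the 4 differences of a whole class from control had an exact permutation p of 0.1, two-sided, the smallest that 3 against 3 can give, and 0.214 adjusted over 15 such tests. Intergenic noncoding RNAs summed to 2576 ± 47.6, 2523 ± 11.3 and 2566 ± 28.9 CPM. The nuclear noncoding RNA MALAT1 stood at 11938 ± 1295, 8926 ± 1703 and 10243 ± 2058 CPM, and NEAT1 at 667 ± 129, 649 ± 23.7 and 543 ± 15.1 CPM.

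KCNH2, a voltage-gated potassium channel gene below the filter, had 0 counts in each control library, 12, 17 and 3 with NnK-1, and 0, 2 and 4 with CBRV1-10493. Of the other untested channel genes, 3 were lowest with NnK-1, with group totals for control, NnK-1 and CBRV1-10493 of 19, 4 and 38 for KCNH3, 30, 7 and 20 for KCNG1 and 18, 9 and 28 for KCNH1. FABP7, a fatty acid binding protein of glia and the second in p among the 136 genes of the exchange, ranged within groups from 60.0 to 123 CPM in control libraries, from 33.4 to 173 with NnK-1 and from 43.8 to 135 with CBRV1-10493.

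Interferon-stimulated genes were lower with NnK-1 than in control cells (mean log2 difference -0.41, adjusted p = 0.925 with an estimated correlation), and most of this difference lies in 1 control library. ISG15 stood at 79.2 CPM in control replicate 2 against 19.2 and 24.4 CPM in the other two, and IFI6 at 98.6 against 42.1 and 37.0 CPM. Without that library the mean difference was -0.073 and the call ended (camera adjusted p = 0.932, range over 15 alternatives 3.55e-06 to 0.932), so a high level of these genes in 1 control library may account for the call; what raised them there was not tested. Against the other two control libraries, 11.8% of the 34 members (4 genes, exact 95% interval 3.30% to 27.5%) had all NnK-1 libraries below, where chance gives 10%. This interval takes the members as independent, while their estimated correlation was 0.357, so it is too narrow. An effect of NnK-1 on these genes stays open, since this interval holds the chance value and shares well above it, as a wider one would.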
